A study of Arabidopsis thaliana with 44 samples.

How the data were processed

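Total RNA from Arabidopsis inflorescences was measured on 44 one-colour arrays of 22810 probe sets. Per the labels, RNA was extracted with TRIzol, purified on a Qiagen column and labelled with an Ambion amplification kit. The authors deposited log2 values for each array, from 3.08 to 14.5 with no missing value. Their background correction, summarization, normalization and reference set are not given in the sources used here. Arrays give no counts, so their number limits the precision.

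The median of the deposited log2 values lay between 6.91 and 7.01 on 38 arrays and between 7.39 and 7.44 on the 6 arrays of the rdr6-15 set, a span of 0.531. By a rule fixed before the data were examined, a span above 0.3 led to quantile normalization of all arrays together. The rdr6-15 set thus stood apart as deposited, so no count of calls between its Col-0 arrays and the other Col-0 sets is given, and a level set across them is named as one. No arrays held identical values, and the highest correlation of 2 arrays was 0.998. The first 2 principal components held 31.5% and 19.2% of the variance and set most control sets apart, though the arrays for hyl1-2 and hst-15 overlapped with those for rdr6-15 on both.

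The groups, control sets and tests were fixed at the same point. After 64 control probe sets were set aside, 22746 were tested with limma 3.58.1 in R 4.3.3, with a mean per group over all arrays, lmFit and eBayes with a trend of the prior variance, 29 residual and 5.06 prior degrees of freedom. Each mutant was set against the controls its labels name, and dcl1-7 was the mean of both set effects with equal weight. All groups share 1 fitted spread per probe set, which is too small for noisier arrays and too large for quieter ones. The root mean square residual ran from 0.181 to 0.423 in the second dcl1-7 set with its Ler arrays. In the set of hyl1-2 and hst-15 it ran from 0.0791 to 0.172. A probe set was called at a Benjamini-Hochberg adjusted p under 0.05. Log2 fold changes are mutant minus control.

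Gene names came from the platform's annotation. 13513 probe sets (59.4%) had 1 gene, 503 had several and 8730 (38.4%) were not listed, and 13436 matched a gene of assembly TAIR10.1, used for current names, gene types and neighbours only. Genes are named by a rule fixed beforehand: in each mutant the 10 largest rises and falls among called probe sets with 1 gene whose mutant arrays all lie on one side of the control arrays, and from each fixed list the members with the smallest p, up to 4, or 10 for microRNA and PPR targets; between mutants, 5 each way. Largest rises and falls are those of this rule. With 3 arrays against 3, chance puts 10% of probe sets wholly on one side.

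At the same time 21 gene lists were fixed, of which 8 had at least 3 measured genes: microRNA targets, PPR targets, meristem and organ polarity, tapetum and pollen wall, mature pollen, photosynthesis, auxin response, and flavonoid and anthocyanin synthesis. 10 of 94 microRNA target genes had a named probe set. Measured genes are those with a probe set of 1 named gene, so others may be on the array without a name. Each list was tested in 9 mutants with limma's camera at a preset correlation of 0.01, and again with an estimated one. 21 of the 72 tests were called and 3 of them with an estimated correlation: microRNA targets in dcl1-7 and hen1-1 and the tapetum and pollen wall list in hst-15. In 9 tests the median, mean and test direction were not of one sign, and 0 of these were called. A further 17 lists were chosen after the data were seen, and 29 of their 153 tests were called, 3 with an estimated correlation.

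Overlaps of calls were set beside the number expected of independent lists, and for mutants with shared controls beside 100 simulated draws of unchanged groups. Calls of probe sets in dcl1-7, hyl1-2 and rdr6-15 and a list test in hen1-1 were tested on simulated data. Each probe set had 1 mean over all groups and 1 fitted spread, with independent noise on each array. Differences between control sets, noisier arrays and correlation between genes were not simulated, so the recovery in these data may be lower. For dcl1-7, 65 of 67 probe sets changed by 1 log2 unit were recovered, among 22746; for hyl1-2, 61 of 67 at 1 log2 unit and 34 of 67 at 0.5; for rdr6-15, 62 of 67 at 1 log2 unit. In these simulations unchanged probe sets made up 3.61%, 2.42% and 5.95% of the calls.

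Alternatives fixed beforehand were the values as deposited, array medians subtracted, leaving out probe sets in the lowest 40% of mean signal, a prior without trend, array weights, only the arrays of the control set, all wild-type arrays of the accession as controls, a change of at least 2-fold, each array left out, either dcl1-7 set alone, an estimated correlation and, for lists, only probe sets without a letter suffix. Adding an offset was not applied since the values were already on the log2 scale. Leaving out Ler replicate 9 in all comparisons was added after the data were seen. No label tied replicate numbers to one another across groups.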

Results

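Transcript levels were measured in Arabidopsis thaliana inflorescences, stages 1 to 12, of 9 mutants in genes that make or handle small RNAs. The 44 one-colour arrays fell into 15 groups of 3 arrays, except the second set of dcl1-7 with 2. DCL1 is the RNase III enzyme that cuts microRNA precursors, HYL1 is its double-stranded RNA-binding partner, HEN1 methylates the ends of small RNAs and HST is an exportin-5 homologue. DCL2 and DCL3 are further Dicer-like enzymes that make short interfering RNAs, and RDR1, RDR2 and RDR6 are RNA-dependent RNA polymerases. The mutants were dcl1-7, in a first and a second set, hen1-1, hyl1-2, hst-15, dcl2-1, dcl3-1, rdr1-1, rdr2-1 and rdr6-15. The labels assigned each mutant to its own wild-type arrays, in 5 control sets. Landsberg erecta (Ler) served dcl1-7 and hen1-1, and Columbia (Col-0) served the others. Changes in mutants that share control arrays are not independent of one another, since the level in those arrays enters each. The labels did not say that replicate arrays came from separate plants, so p-values measure the spread between these arrays, which may be technical. None of the 9 mutated genes had a named probe set here, so the labels could not be checked against the level of the mutated gene.

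Wild-type arrays differed between control sets. Between the Ler arrays for the first dcl1-7 set and those for the second, 9397 of 22746 probe sets were called by limma (4359 higher and 5038 lower in the first). The count was 5806 with only the arrays of the control set. Between the Col-0 arrays for hyl1-2 and hst-15 and those for dcl2-1, dcl3-1, rdr1-1 and rdr2-1, 6369 were called (3302 higher and 3067 lower in the former). The count was 10997 with array weights. Whatever sets these apart cannot be told from batch, so the log2 fold changes of every mutant are against the controls of its own set. The 3′ minus 5′ log2 signal of the actin control probe sets lay between 0.55 and 0.86 in the set of hyl1-2 and hst-15 and between 1.02 and 2.23 in that of dcl2-1, dcl3-1, rdr1-1 and rdr2-1. Ler replicate 9, of the second dcl1-7 set, had a root mean square residual of 0.423, against a median of 0.119 over all arrays.

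**Figure D1:**
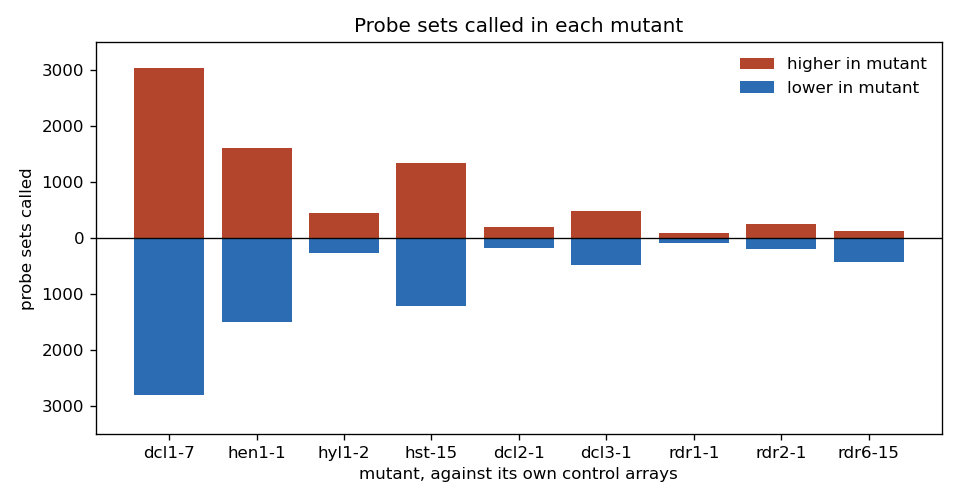
Number of probe sets called in each mutant against its own control arrays by limma at an adjusted p under 0.05, with those called higher above the zero line and those called lower below it. The bars run from 182 called probe sets in rdr1-1 to 5853 in dcl1-7, which has 5 mutant arrays where the others have 3. All groups share 1 spread per probe set. The order of the mutants depends on the setting: with only the arrays of the control set, hen1-1 and hst-15 had more calls than dcl1-7.

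The first comparison asked which transcripts change with loss of DCL1 function. In dcl1-7, of the 10 measured microRNA target genes 5 rose and 5 were not called, with 5 higher when adjusted over the list alone. The MADS-box gene AGL16 had the smallest p among them (log2 fold change 1.44 ± 0.08 (SE), adjusted p = 1.99e-15). Its log2 signal went from 8.03 ± 0.13 to 9.29 ± 0.12 in the first set (SD, n = 3) and from 7.41 ± 0.21 (SD, n = 3) to 9.02 ± 0.08 (SD, n = 2) in the second. The class III homeodomain-leucine zipper gene PHV (0.87), the F-box gene LCR (0.52), the ATP sulfurylase gene APS3 (0.55) and CCS, the copper chaperone of superoxide dismutase (0.95), rose as well. The list shifted up (median 0.35, camera adjusted p = 0.00235, and adjusted p = 0.0194 with an estimated correlation), and was not called in the first set alone (median 0.32, adjusted p = 0.0546). SMZ (-0.053) and SNZ (-0.048) of this list were not called. The PPR list, described with hyl1-2, was not called in dcl1-7 (adjusted p = 0.652), where 2 of its 10 measured members rose. These members, AT1G63080 (0.30) and AT1G12775 (0.35), were not called with only the arrays of the control set. The log2 fold changes of dcl1-7 are means over both sets.

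Of the 4 mature pollen genes 3 fell in dcl1-7, with 4 lower when adjusted over the list alone. They were ANX1 (-0.32), MGH3, a histone H3 gene of the male gamete (-1.01, adjusted p = 2.95e-07), and ANX2, a receptor kinase gene of the pollen tube (-0.95, adjusted p = 0.000816). The list shifted down (median -0.63, camera adjusted p = 0.00436, and adjusted p = 0.173 with an estimated correlation). Of the 4 tapetum and pollen wall genes 2 fell, with 3 lower when adjusted over the list alone (median -0.49, camera adjusted p = 0.0331, and adjusted p = 0.275 with an estimated correlation): AMS, a basic helix-loop-helix gene of the tapetum (-0.75), and the sporocyte regulator SPL (-0.59). Of the 4 meristem and organ polarity genes 2 fell and 1 rose. INO, a YABBY gene of the outer integument of the ovule (log2 fold change -1.21 ± 0.13 (SE), adjusted p = 4.91e-09), and YAB5 (-0.62) fell, YAB3 rose (0.37), and this list was not called (adjusted p = 0.241). AT3G26860 (-3.67), LEA (-3.65) and AT5G61605 (-3.60) had the largest falls by the naming rule, and AT4G17470 (2.33), AT5G52760 (2.27) and AT5G52790 (1.94) the largest rises. In dcl1-7 the mature pollen list was not called in the second set alone (median -0.34, adjusted p = 0.169). In dcl1-7 the tapetum and pollen wall list was not called with all wild-type arrays of the accession as controls (median -0.49, adjusted p = 0.065), in the first set alone (median -0.079, adjusted p = 0.723), without Ler replicate 6 (median -0.48, adjusted p = 0.0535), without Ler replicate 8 (median -0.50, adjusted p = 0.0592) or without dcl1-7 replicate 15 (median -0.46, adjusted p = 0.0589). YAB3 was not called without dcl1-7 replicate 17 (0.30), nor with only the arrays of the control set (0.37), nor in the second set alone (0.29), nor with array weights (0.26). AMS (-0.40) and SPL (0.062, of the opposite sign) were not called in the first set alone. ANX1 (-0.21) and ANX2 (-0.47) were not called in the second set alone.

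Across the array, dcl1-7 differed from Ler in 5853 of 22746 probe sets (3044 higher and 2809 lower), 177 of them at least 2-fold higher and 419 at least 2-fold lower. The count was 2598 with only the arrays of the control set and 2875 with all wild-type arrays of the accession as controls. The first set alone gave 5374 calls and the second 4263. Of these, 380 were higher in both sets, against 249.9 expected of independent lists, and 699 were lower in both, against 249.7. A further 202 were higher in the first and lower in the second, and 141 the reverse. The correlation of log2 fold changes across probe sets, which are not independent replicates, was 0.353. The effect itself differed between the sets for 3558 probe sets (1941 higher and 1617 lower in the first). This test used the spread shared by all groups. The number was 2172 with array weights and 918 with only the arrays of the control set, which use the spread of these sets alone. It was 1954 without dcl1-7 replicate 16. With array medians subtracted the median of all probe sets in this contrast was 0.108.

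For HEN1 the same question was asked. In hen1-1, of the 10 measured microRNA target genes 5 rose and 5 were not called, with 5 higher when adjusted over the list alone (median 0.51, camera adjusted p = 0.000611, and adjusted p = 0.0136 with an estimated correlation). AGL16 rose (log2 fold change 1.03 ± 0.11 (SE), adjusted p = 1.16e-08) from 8.03 ± 0.13 to 9.06 ± 0.06 (SD, n = 3), and so did LCR (0.67), APS3 (0.76), PHV (0.66) and ARPN, the plantacyanin gene (0.76, adjusted p = 0.0125). CCS was at -0.092 and not called. AGO7, an ARGONAUTE gene of the trans-acting siRNA pathway, rose (0.59, adjusted p = 0.00253). The largest falls included LTI30, a dehydrin gene (-3.62), HIS1-3, a linker histone gene (-2.83), and COR15B (-2.28). AT5G19880 (3.74), AT4G11290 (3.39) and AT1G27570 (3.15) had the largest rises. ARPN was not called without Ler replicate 5 (0.71) or hen1-1 replicate 26 (0.65). HIS1-3 (-2.26) was not called with all wild-type arrays of the accession as controls.

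The tapetum genes AMS (-1.13) and AT5G07230 (-1.07) fell in hen1-1, and so did YAB5 (-0.67). Of the 4 tapetum and pollen wall genes, 1 was higher and 2 were lower in hen1-1 at an unadjusted p under 0.05 by limma. The tapetum and pollen wall list (median -0.61, camera adjusted p = 0.122, and adjusted p = 0.416 with an estimated correlation), the mature pollen list (adjusted p = 0.0543) and the PPR list (adjusted p = 0.145) were not called. Of the 10 measured PPR genes 1 rose in hen1-1. Across the array, hen1-1 differed from Ler in 3107 of 22746 probe sets (1613 higher and 1494 lower), 249 of them at least 2-fold higher and 360 at least 2-fold lower. The count was 6837 with array weights and 4804 with only the arrays of the control set. YAB5 (-0.36) was not called with all wild-type arrays of the accession as controls.

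The first dcl1-7 set and hen1-1, which share Ler arrays, were then compared with each other. CCS was higher in dcl1-7 (log2 difference 1.09, adjusted p = 0.000587), a gene chosen after its values were seen. AT3G05730 (4.95), AT4G17470 (2.91) and ECS1 (2.42) were higher in dcl1-7, and GILT (-3.47), AT5G19880 (-3.24) and AT4G11290 (-3.13) were lower there than in hen1-1. A difference was called for 3451 of 22746 probe sets (1790 higher and 1661 lower), and with array medians subtracted for 2842 higher and 1571 lower. The count was 6898 with array weights and 5664 with only the arrays of the control set. It was 1886 without dcl1-7 replicate 13 and 1994 without hen1-1 replicate 26. For the microRNA target list no difference was called (median 0.069, mean -0.20 and a test direction of down, adjusted p = 0.452, and adjusted p = 0.59 with an estimated correlation). Of the calls in dcl1-7 over both sets and in hen1-1, 736 were higher in both, against 216 expected of independent lists, 904 lower in both, against 184, and 82 went opposite ways. The number that went the same way was 694 with only the arrays of the control set and 1089 with all wild-type arrays of the accession as controls. The correlation of log2 fold changes across probe sets was 0.583 and the covariance 0.0747, against 0.334 and 0.00530 for unchanged groups simulated against the shared Ler arrays. Part of the excess may come from these shared controls.

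In hyl1-2, of the 10 measured microRNA target genes 2 rose and 8 were not called, with 2 higher when adjusted over the list alone. They were AGL16 (log2 fold change 0.93 ± 0.11 (SE), adjusted p = 5.15e-07), which went from 7.03 ± 0.01 to 7.96 ± 0.09 (SD, n = 3), and PHV (0.58, adjusted p = 0.00623). The list shifted up (median 0.072, camera adjusted p = 0.026, and adjusted p = 0.0678 with an estimated correlation), and was not called without hyl1-2 replicate 32 (median 0.0077, adjusted p = 0.0626) or with all wild-type arrays of the accession as controls (median 0.087, adjusted p = 0.0671). Without hyl1-2 replicate 31 its median was 0.14. The PPR list holds pentatricopeptide repeat genes targeted by miR161, miR400 or trans-acting siRNAs. Of its 10 measured members 3 rose, with 5 higher when adjusted over the list alone (median 0.16, camera adjusted p = 8.91e-05, and adjusted p = 0.132 with an estimated correlation). AT1G63150 (1.40, adjusted p = 2.89e-05), AT1G63080 (0.63, adjusted p = 0.00021) and AT1G63400 (0.20, adjusted p = 0.0474) were these, and a probe set may read several of these closely related copies. The mature pollen list shifted down (median -0.42, camera adjusted p = 0.00889, and adjusted p = 0.237 with an estimated correlation), where limma called 0 of 4 members (0 higher and 3 lower at an unadjusted p under 0.05), and 3 lower when adjusted over the list alone. AT2G43620 (2.07), AT1G55450 (1.97) and AT1G65500 (1.89) had the largest rises, and scpl31 (-1.58), AT2G20560 (-1.58) and the expansin gene EXPA8 (-1.28) were among the falls. AT1G63400 was not called without Col-0 replicate 1 (0.17), Col-0 replicate 3 (0.19), hyl1-2 replicate 30 (0.20), hyl1-2 replicate 31 (0.16) or hyl1-2 replicate 32 (0.23), nor with the values as deposited (0.18), nor with array medians subtracted (0.17), nor with a prior without trend (0.20). AT1G55450 (1.33), scpl31 (-0.79) and AT2G20560 (-0.88) were not called with all wild-type arrays of the accession as controls.

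Across the array, hyl1-2 differed from Col-0 in 710 of 22746 probe sets (443 higher and 267 lower), 95 of them at least 2-fold higher and 41 at least 2-fold lower. The count was 3667 with array weights, 2803 with only the arrays of the control set and 1283 without Ler replicate 9 in any comparison. It was 382 without Col-0 replicate 1, 429 without Col-0 replicate 2, 449 without Col-0 replicate 3, 398 without hyl1-2 replicate 30, 464 without hyl1-2 replicate 31 and 466 without hyl1-2 replicate 32. Of the calls in hyl1-2 and in dcl1-7, which share no control arrays, 243 were higher in both, against 59.3 expected of independent lists, 104 lower in both, against 33.0, and 39 went opposite ways. The 347 that went the same way moved with the setting. This number was 1159 with array weights and 570 without Ler replicate 9 in any comparison. It was 199 without Col-0 replicate 1, 214 without Col-0 replicate 2, 225 without Col-0 replicate 3, 570 without Ler replicate 9 and 187 without hyl1-2 replicate 30. The correlation of log2 fold changes across probe sets was 0.433.

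In hst-15, 3 of the 4 tapetum and pollen wall genes fell, with 4 lower when adjusted over the list alone (median -1.18, camera adjusted p = 4.12e-05, and adjusted p = 0.0369 with an estimated correlation). AMS fell (log2 fold change -2.04 ± 0.21 (SE), adjusted p = 1.43e-08) from 7.93 ± 0.05 to 5.89 ± 0.19 (SD, n = 3), and AT5G07230 (-1.88, adjusted p = 1.77e-07) and SPL (-0.49) fell too. Of the mature pollen genes 2 of 4 fell, MGH3 (-0.63) and TUA1, a tubulin gene (-0.46), with 3 lower when adjusted over the list alone (median -0.54, camera adjusted p = 0.0242, and adjusted p = 0.275 with an estimated correlation). In hst-15 the mature pollen list was not called without hst-15 replicate 27 (median -0.44, adjusted p = 0.0836). Of the 10 measured microRNA target genes 3 rose and 7 were not called, with 4 higher when adjusted over the list alone (median 0.25, camera adjusted p = 0.0196, and adjusted p = 0.0514 with an estimated correlation). Those that rose were ARPN (log2 fold change 1.35 ± 0.21 (SE), adjusted p = 2.31e-05), PHV (0.57) and LCR (0.37). AGL16 was at 0.015 and not called. The PPR list was not called (adjusted p = 0.241), where 2 of its 10 measured members rose, AT1G63150 and AT5G41170. Neither was called with the values as deposited (0.55 and 0.13). AT5G52160 (-2.35), AT3G07450 (-2.15) and AT5G62080 (-2.11) had the largest falls, and AT1G55450 (3.26), AT4G36500 (3.21) and AT5G52760 (2.86) the largest rises. WRKY53, a transcription factor gene of senescence and defence, rose as well (2.61, adjusted p = 7.89e-07). SPL was not called without Col-0 replicate 1 (-0.46) or hst-15 replicate 29 (-0.40), nor with all wild-type arrays of the accession as controls (-0.47). MGH3 was not called without hst-15 replicate 27 (-0.59) or hst-15 replicate 28 (-0.61), nor with all wild-type arrays of the accession as controls (-0.34). TUA1 was not called without Col-0 replicate 1 (-0.47), Col-0 replicate 3 (-0.38), hst-15 replicate 27 (-0.39) or hst-15 replicate 28 (-0.47), nor with all wild-type arrays of the accession as controls (-0.41). LCR was not called without Col-0 replicate 1 (0.32).

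Across the array, hst-15 differed from Col-0 in 2554 of 22746 probe sets (1348 higher and 1206 lower), 304 of them at least 2-fold higher and 301 at least 2-fold lower. The count was 7661 with array weights and 5499 with only the arrays of the control set. It was 1634 without hst-15 replicate 29.

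The mutants hyl1-2 and hst-15, which share Col-0 arrays, were compared with each other. AGL16 was higher in hyl1-2 (log2 difference 0.92, adjusted p = 8.56e-07), a comparison chosen after its value was seen. AT5G17340 (2.25), AT3G07450 (2.13) and AT5G62080 (2.03) were among the largest differences with hyl1-2 higher, and each of these was called lower in hst-15 than in Col-0 and not called in hyl1-2. WRKY53 (-2.11), AR781 (-1.91) and AT5G18470 (-1.79) were lower in hyl1-2. A difference was called for 750 of 22746 probe sets (361 higher and 389 lower). The count was 4157 with array weights, 2197 with only the arrays of the control set and 1201 without Ler replicate 9 in any comparison. It was 352 without hst-15 replicate 28, 330 without hst-15 replicate 29, 476 without hyl1-2 replicate 30, 463 without hyl1-2 replicate 31 and 387 without hyl1-2 replicate 32. The PPR list was higher in hyl1-2 (median 0.13, camera adjusted p = 0.0102, and adjusted p = 0.283 with an estimated correlation), and not called without hyl1-2 replicate 31 (median 0.067, adjusted p = 0.0873). For the microRNA target list no difference was called (median -0.061, adjusted p = 0.388, and adjusted p = 0.424 with an estimated correlation). Of the calls against Col-0, 308 were higher in both mutants, against 26.3 expected of independent lists, 191 lower in both, against 14.2, and 1 went opposite ways. The number that went the same way was 2570 with array weights, 2027 with only the arrays of the control set and 910 without Ler replicate 9 in any comparison. It was 264 without Col-0 replicate 1, 311 without Col-0 replicate 2, 321 without Col-0 replicate 3 and 291 without hyl1-2 replicate 30. The correlation across probe sets was 0.713 and the covariance 0.0582, against 0.501 and 0.0105 for unchanged groups simulated against the shared controls. Part of the excess may come from these controls.

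**Figure D2:**
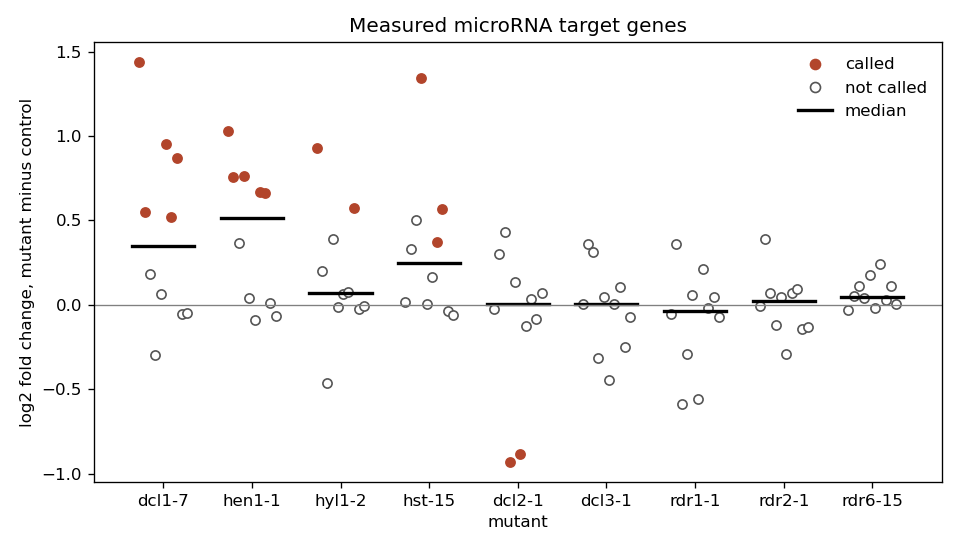
Log2 fold change, mutant minus control, of each of the 10 measured microRNA target genes in each mutant, in the same gene order, with called genes filled and the median of the list as a black line. The medians are 0.35 in dcl1-7, 0.51 in hen1-1, 0.072 in hyl1-2 and 0.25 in hst-15, and lie between -0.034 and 0.045 in the other mutants.

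The mutants dcl2-1, dcl3-1, rdr1-1 and rdr2-1 share a set of Col-0 arrays. QQS, an orphan gene of starch metabolism, rose in rdr2-1 (log2 fold change 3.65 ± 0.29 (SE), adjusted p = 7.51e-11) from 7.84 ± 0.14 to 11.49 ± 0.16 (SD, n = 3) and in dcl2-1 (2.93, adjusted p = 9.73e-08). It was at -0.85 in dcl3-1 and 0.49 in rdr1-1, not called. QQS was also called higher in hen1-1 (1.09) and lower in hyl1-2 (-1.20) and hst-15 (-1.15), against other control arrays. QQS in hen1-1 was not called without Ler replicate 4 (0.97) or hen1-1 replicate 24 (0.45), nor with only the arrays of the control set (1.09), nor with all wild-type arrays of the accession as controls (1.07). QQS in hyl1-2 was not called without Col-0 replicate 1 (-1.16), Col-0 replicate 3 (-1.19) or hyl1-2 replicate 32 (-1.08). QQS in hst-15 was not called without hst-15 replicate 29 (-0.97). In rdr2-1 the transcribed pseudogene RSU1 (2.63), the pseudogene AT2G03080 (2.07) and AT2G13770 (1.85) rose and AT1G52000 fell (-2.35). In dcl3-1, AT3G55920 fell (log2 fold change -3.30 ± 0.24 (SE), adjusted p = 3.32e-11), and AT1G68620 (1.95), AT1G70270 (1.94) and the beta-glucosidase gene BGLU28 (1.79) rose. In dcl2-1, AT3G23450 (-1.55), AT5G52160 (-1.52) and AT5G62080 (-1.38) fell. In rdr1-1 the asparaginase gene ASPGB1 rose (1.36, adjusted p = 0.00082) and AT3G23450 fell (-1.77).

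Of the 4 tapetum and pollen wall genes 3 fell in dcl2-1, AMS (-0.82), AT5G07230 (-0.99) and SPL (-0.60), with 3 lower when adjusted over the list alone (median -0.71, camera adjusted p = 0.000144, and adjusted p = 0.0514 with an estimated correlation). In rdr2-1 2 fell, AMS (-0.84) and SPL (-0.54), with 3 lower when adjusted over the list alone (median -0.63, camera adjusted p = 0.000144, and adjusted p = 0.0514 with an estimated correlation). AMS in dcl2-1 was not called without Col-0 replicate 10 (-0.83), Col-0 replicate 11 (-0.74), Col-0 replicate 12 (-0.89), dcl2-1 replicate 18 (-0.86) or dcl2-1 replicate 20 (-0.58), nor with only the arrays of the control set (-0.82), nor with all wild-type arrays of the accession as controls (-0.69). AT5G07230 in dcl2-1 was not called without Col-0 replicate 10 (-0.99), Col-0 replicate 11 (-0.86) or dcl2-1 replicate 20 (-0.67), nor with only the arrays of the control set (-0.99). SPL in dcl2-1 was not called without Col-0 replicate 12 (-0.53), dcl2-1 replicate 19 (-0.47) or dcl2-1 replicate 20 (-0.57), nor with only the arrays of the control set (-0.60), nor with all wild-type arrays of the accession as controls (-0.50). AMS in rdr2-1 was not called without Col-0 replicate 10 (-0.85), Col-0 replicate 11 (-0.76), rdr2-1 replicate 37 (-0.65) or rdr2-1 replicate 38 (-0.82), nor with only the arrays of the control set (-0.84), nor with all wild-type arrays of the accession as controls (-0.71). SPL in rdr2-1 was not called without Col-0 replicate 10 (-0.55), Col-0 replicate 12 (-0.48), rdr2-1 replicate 37 (-0.50) or rdr2-1 replicate 38 (-0.50), nor with only the arrays of the control set (-0.54), nor with all wild-type arrays of the accession as controls (-0.44).

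The tapetum and pollen wall list also shifted down in dcl3-1 (median -0.37, camera adjusted p = 0.026, and adjusted p = 0.25 with an estimated correlation), where limma called 0 of 4 members (0 higher and 3 lower at an unadjusted p under 0.05), and 1 lower when adjusted over the list alone. In rdr1-1 it shifted down as well (median -0.25, camera adjusted p = 0.0492, and adjusted p = 0.281 with an estimated correlation), where limma called 0 of 4 members (0 higher and 2 lower at an unadjusted p under 0.05), and 0 when adjusted over the list alone. The falls of this list in dcl2-1, rdr2-1, dcl3-1 and rdr1-1 share the same Col-0 arrays, so they are not independent of one another. In dcl3-1 the tapetum and pollen wall list was not called with array weights (median -0.34, adjusted p = 0.0542), with only the arrays of the control set (median -0.37, adjusted p = 0.0943), with all wild-type arrays of the accession as controls (median -0.33, adjusted p = 0.094) or without dcl3-1 replicate 22 (median -0.27, adjusted p = 0.132). In rdr1-1 the tapetum and pollen wall list was not called with array weights (median -0.23, adjusted p = 0.208), with only the arrays of the control set (median -0.25, adjusted p = 0.126), with all wild-type arrays of the accession as controls (median -0.26, adjusted p = 0.16), without Col-0 replicate 10 (median -0.25, adjusted p = 0.0634), without Col-0 replicate 11 (median -0.25, adjusted p = 0.1), without rdr1-1 replicate 33 (median -0.22, adjusted p = 0.221) or without rdr1-1 replicate 34 (median -0.21, adjusted p = 0.14). The mature pollen list, at -0.35 in rdr1-1 without rdr1-1 replicate 33, shifted up in dcl3-1 (median 0.28, camera adjusted p = 0.028, and adjusted p = 0.279 with an estimated correlation), with MGH3 called (0.72) and 1 higher when adjusted over the list alone, and down in rdr1-1 (median -0.22, camera adjusted p = 0.0331, and adjusted p = 0.293 with an estimated correlation), where limma called 0 of 4 members (0 higher and 2 lower at an unadjusted p under 0.05), and 2 lower when adjusted over the list alone. In dcl3-1 the mature pollen list was not called with only the arrays of the control set (median 0.28, adjusted p = 0.0954), without Col-0 replicate 11 (median 0.17, adjusted p = 0.0762) or without dcl3-1 replicate 22 (median 0.24, adjusted p = 0.077). In rdr1-1 the mature pollen list was not called with only the arrays of the control set (median -0.22, adjusted p = 0.136), with all wild-type arrays of the accession as controls (median -0.096, adjusted p = 0.828), without Col-0 replicate 10 (median -0.18, adjusted p = 0.0975), without Col-0 replicate 12 (median -0.21, adjusted p = 0.0767), without rdr1-1 replicate 34 (median -0.17, adjusted p = 0.122) or without rdr1-1 replicate 35 (median -0.13, adjusted p = 0.125). MGH3 in dcl3-1 was not called without Col-0 replicate 11 (0.65) or dcl3-1 replicate 21 (0.63), nor with only the arrays of the control set (0.72).

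The flavonoid and anthocyanin list shifted up in dcl2-1 (median 0.38, camera adjusted p = 0.00889, and adjusted p = 0.173 with an estimated correlation) and dcl3-1 (median 0.45, camera adjusted p = 0.00436, and adjusted p = 0.173 with an estimated correlation). DFR, the dihydroflavonol reductase gene, was the called member in both (0.80 and 0.97), with 2 higher when adjusted over the list alone in each. In rdr2-1 the list shifted up too (median 0.29, camera adjusted p = 0.0331, and adjusted p = 0.275 with an estimated correlation), where limma called 0 of 3 members (2 higher and 0 lower at an unadjusted p under 0.05), and 1 higher when adjusted over the list alone. All these rises share the same Col-0 arrays and are not independent of one another. In dcl2-1 the flavonoid and anthocyanin list was not called with all wild-type arrays of the accession as controls (median 0.33, adjusted p = 0.224). In dcl3-1 the flavonoid and anthocyanin list was not called with all wild-type arrays of the accession as controls (median 0.40, adjusted p = 0.105). In rdr2-1 the flavonoid and anthocyanin list was not called with array weights (median 0.31, adjusted p = 0.11), with all wild-type arrays of the accession as controls (median 0.24, adjusted p = 0.428), without Col-0 replicate 11 (median 0.30, adjusted p = 0.0526), without Col-0 replicate 12 (median 0.23, adjusted p = 0.0934) or without rdr2-1 replicate 38 (median 0.16, adjusted p = 0.132). DFR in dcl2-1 was not called without Col-0 replicate 10 (0.86), Col-0 replicate 11 (0.74), Col-0 replicate 12 (0.81), dcl2-1 replicate 19 (0.65) or dcl2-1 replicate 20 (0.78), nor with all wild-type arrays of the accession as controls (0.45), nor with array medians subtracted (0.79). DFR in dcl3-1 was not called without Col-0 replicate 11 (0.90), nor with all wild-type arrays of the accession as controls (0.61).

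The microRNA target list was not called in dcl2-1 (adjusted p = 0.703), dcl3-1 (adjusted p = 0.984), rdr1-1 (adjusted p = 0.817) or rdr2-1 (adjusted p = 0.984). Its members ARPN (-0.93) and CCS (-0.88) fell in dcl2-1. ARPN was not called without Col-0 replicate 10 (-0.84), Col-0 replicate 11 (-0.996) or dcl2-1 replicate 20 (-0.93). CCS was not called without Col-0 replicate 10 (-0.82), Col-0 replicate 11 (-0.87), Col-0 replicate 12 (-0.95), dcl2-1 replicate 18 (-0.80) or dcl2-1 replicate 20 (-0.85). The PPR list was not called in these mutants (smallest adjusted p = 0.673).

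Counts in this set moved with single arrays. Of all 44 arrays dcl2-1 replicate 19 had the highest 3′ minus 5′ log2 signal of actin (2.23) and the lowest log2 signal of 25S ribosomal RNA (4.94). In dcl2-1, 363 probe sets were called (196 higher and 167 lower). The count was 1487 with array weights, 729 with all wild-type arrays of the accession as controls and 849 without Ler replicate 9 in any comparison. It was 183 without Col-0 replicate 10, 72 without Col-0 replicate 11, 237 without Col-0 replicate 12 and 72 without dcl2-1 replicate 20. In dcl3-1, 965 were called (494 higher and 471 lower). The count was 3373 with array weights, 1939 with all wild-type arrays of the accession as controls and 2099 without Ler replicate 9 in any comparison. It was 193 without Col-0 replicate 11, 271 without dcl3-1 replicate 21 and 604 without dcl3-1 replicate 23. In rdr1-1, 182 were called (98 higher and 84 lower), and with the values as deposited 147 higher and 73 lower. The count was 4555 with array weights, 115 with only the arrays of the control set and 675 without Ler replicate 9 in any comparison. It was 63 without Col-0 replicate 10, 77 without Col-0 replicate 11, 67 without Col-0 replicate 12, 705 without rdr1-1 replicate 33, 29 without rdr1-1 replicate 34 and 47 without rdr1-1 replicate 35. In rdr2-1, 458 were called (262 higher and 196 lower). The count was 3565 with array weights, 727 with all wild-type arrays of the accession as controls and 915 without Ler replicate 9 in any comparison. It was 252 without Col-0 replicate 10, 181 without Col-0 replicate 11, 271 without Col-0 replicate 12 and 294 without rdr2-1 replicate 38.

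RDR2 and DCL3 act in the heterochromatic siRNA pathway, and their mutants were compared with each other. QQS (4.50), RSU1 (2.69) and AT3G55920 (2.64) were higher in rdr2-1, and AT5G26060 (-1.62) was lower. A difference was called for 390 of 22746 probe sets (105 higher and 285 lower). The count was 180 without dim probe sets, 2383 with array weights and 616 without Ler replicate 9 in any comparison. It was 176 without dcl3-1 replicate 21, 259 without dcl3-1 replicate 22 and 141 without rdr2-1 replicate 38. Of the calls against Col-0, 116 were higher in both mutants, against 5.69 expected of independent lists, 81 lower in both, against 4.06, and 0 went opposite ways. The number that went the same way was 1408 with array weights, 376 with all wild-type arrays of the accession as controls and 478 without Ler replicate 9 in any comparison. It was 112 without Col-0 replicate 10, 38 without Col-0 replicate 11, 128 without Col-0 replicate 12 and 106 without dcl3-1 replicate 21. The correlation across probe sets was 0.610 and the covariance 0.0314, against 0.501 and 0.0106 for unchanged groups simulated against the shared Col-0 arrays. The other pairs of mutants against these arrays had correlations of 0.745 (dcl2-1 and dcl3-1), 0.655 (dcl2-1 and rdr2-1), 0.649 (rdr1-1 and rdr2-1), 0.492 (dcl2-1 and rdr1-1) and 0.478 (dcl3-1 and rdr1-1), against 0.498 to 0.501 simulated. Their covariances, in the same order, were 0.0376, 0.0287, 0.0270, 0.0201 and 0.0229, against 0.0105 to 0.0106 simulated. Calls went the same way for 235 probe sets in dcl2-1 and dcl3-1, against 197 in dcl3-1 and rdr2-1. Differences between pairs were not tested. Part of the excess may come from these arrays.

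In rdr6-15 more probe sets fell than rose. AT4G29780 (log2 fold change -4.09 ± 0.70 (SE), adjusted p = 0.000309), AT3G01830 (-3.94) and STZ, a zinc-finger gene of the cold and salt response (-3.92, adjusted p = 2.01e-05), had the largest falls. STZ went from 9.53 ± 0.59 to 5.61 ± 0.43 (SD, n = 3). AT5G19240 (-3.43), the calmodulin-like gene CML38 (-3.29) and the AP2/ERF gene ORA47 (-2.92) fell too, and AT3G55920 (1.66) and BCAT4 (1.49) had the largest rises. AT4G29780 (-2.16), AT3G01830 (-1.47), CML38 (-1.62), ORA47 (-1.54), AT3G55920 (0.80) and BCAT4 (1.23) were not called with all wild-type arrays of the accession as controls. In the same arrays the control probe set for 25S ribosomal RNA was at 7.89 in rdr6-15 and 6.77 in Col-0 (adjusted p = 0.00215). Across the array, rdr6-15 differed from Col-0 in 548 of 22746 probe sets (122 higher and 426 lower), 9 of them at least 2-fold higher and 233 at least 2-fold lower. The count was 3585 with array weights, 2081 with all wild-type arrays of the accession as controls and 854 without Ler replicate 9 in any comparison. It was 289 without Col-0 replicate 40 and 341 without Col-0 replicate 41.

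For the microRNA target list in rdr6-15, limma called 0 of 10 members (2 higher and 0 lower at an unadjusted p under 0.05), and 0 when adjusted over the list alone, and the list was not called (median 0.045, camera adjusted p = 0.42, and adjusted p = 0.515 with an estimated correlation). The log2 fold changes of the list, each against the mutant's own controls and in different accessions, were higher in dcl1-7 than in rdr6-15 (median difference 0.17, camera adjusted p = 0.0104, and adjusted p = 0.029 with an estimated correlation), and not called without dcl1-7 replicate 16 (median 0.12, adjusted p = 0.0613). This difference had a median of 0.11 without Ler replicate 6 and 0.26 without Col-0 replicate 39. The PPR list shifted up in rdr6-15 with 2 of 10 members called, and 2 higher when adjusted over the list alone (median 0.056, camera adjusted p = 0.0426, and adjusted p = 0.416 with an estimated correlation). It was not called without Col-0 replicate 39 (median 0.047, adjusted p = 0.0798), rdr6-15 replicate 43 (median 0.061, adjusted p = 0.114) or rdr6-15 replicate 44 (median 0.027, adjusted p = 0.286), with a prior without trend (adjusted p = 0.0567) or with only the arrays of the control set (adjusted p = 0.0748). Without rdr6-15 replicate 42 its median was 0.14. The members were AT1G12775 (0.56) and AT1G63080 (0.41). AT1G12775 was not called without Col-0 replicate 39 (0.50), rdr6-15 replicate 43 (0.49) or rdr6-15 replicate 44 (0.52). AT1G63080 was not called without Col-0 replicate 39 (0.37), Col-0 replicate 40 (0.42), Col-0 replicate 41 (0.44), rdr6-15 replicate 43 (0.40) or rdr6-15 replicate 44 (0.36), nor with only the arrays of the control set (0.41). The mature pollen list shifted down (median -0.23, camera adjusted p = 0.028, and adjusted p = 0.279 with an estimated correlation), where limma called 0 of 4 members (0 higher and 1 lower at an unadjusted p under 0.05), and 0 when adjusted over the list alone. In rdr6-15 the mature pollen list was not called with array weights (median -0.22, adjusted p = 0.0651), without Col-0 replicate 39 (median -0.25, adjusted p = 0.0512) or without rdr6-15 replicate 42 (median -0.18, adjusted p = 0.123).

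**Figure D3:**
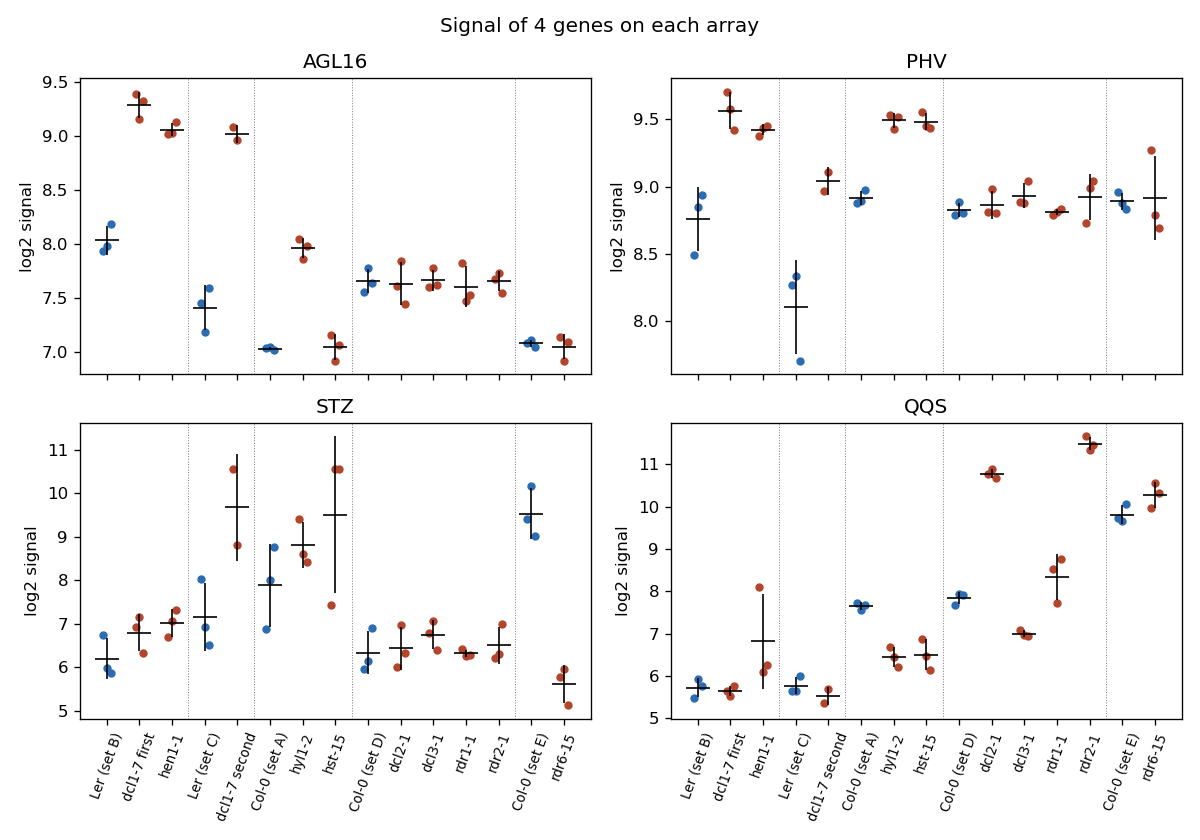
Log2 signal of AGL16, PHV, STZ and QQS on each of the 44 arrays after quantile normalization, by group, with wild-type arrays in blue, mutant arrays in red and dotted lines between control sets; bars are the mean ± SD of a group, and levels are to be compared within a control set. AGL16 lies above its Ler arrays in dcl1-7 and hen1-1, STZ is at 5.61 ± 0.43 in rdr6-15, and QQS is at 11.49 ± 0.16 in rdr2-1.

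The meristem and organ polarity, photosynthesis and auxin response lists were not called in any of the 9 mutants. The smallest adjusted p was 0.0768 for meristem and organ polarity, 0.122 for photosynthesis and 0.0778 for auxin response. The direction and call of each list shift named as called here held with the values as deposited and with array medians subtracted.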

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

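Leaving out Ler replicate 9 was chosen after the data were seen. No group had 4 or more arrays, so no array was tested as an outlier of its group.

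The effect of dcl1-7 differed between its first and second set for 3558 probe sets, by a test of the difference itself, and for fewer with only the arrays of the control set. Without Ler replicate 9, 3832 probe sets differed. This count cannot weigh that array as a cause, since leaving it out also raised counts in comparisons that do not use it. The 2632 of the 3558 probe sets that were called in both fits share this limit. The correlation of log2 fold changes between the sets, which does not use the spread, was 0.356 without that array and 0.353 with it. Against different levels in the Ler arrays alone, the median size of the Ler difference over these probe sets was 0.886 times that of the dcl1-7 difference (0.41 against 0.46). Of 100 splits drawn within the sets, 7 gave as many calls, with 6767 as the highest other, and splits that exchange the labels in a single set turn the mean effect into a difference, so this count cannot exclude chance. The labels name no growth condition that differs between the sets, and no biological explanation was tested.

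Among named genes the difference between the sets was called for SPL, at 1.299 (first minus second), and for PDF1.2, a defensin gene, at -0.67. The control probe set for 25S ribosomal RNA, outside the main measurement, was higher in rdr6-15 than in its Col-0 arrays by 1.115, and that for 5S ribosomal RNA was higher in dcl1-7 by 0.32.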

How the results depend on the processing

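Leaving out Ler replicate 9 in all comparisons was chosen after seeing the data, as were the alternatives for control-set differences, overlaps, list differences, lists other than microRNA and PPR targets, and the differences of AGL16 and CCS between mutants. No paired analysis was possible because replicate numbers are never shared between groups. Of the named gene values, recomputed under each alternative, 3823 kept their direction and their side of the threshold, 505 ended as calls with the same direction and 7 turned. 192 of 277 kept their call without each array in turn, and with 1 array left in a group that array is assumed to vary like the others. Of the counts and the values of the microRNA and PPR target lists, 463 stayed within 1.5 times or on their side of the threshold, 115 counts moved by over 1.5 times and 15 calls of the microRNA and PPR target lists or of their differences between mutants ended. Over all lists, of 50 called shifts 44 ended with an estimated correlation, 20 with all arrays of the accession as controls, 8 with array weights, 6 with only the arrays of the control set, 4 with the first and 4 with the second set alone, 2 with a prior without trend, 1 with array medians subtracted and 1 with the values as deposited. Signal over background was not used here, so weakly expressed genes limit the calls in a way not measured here; the cause of the changes was not tested, except where fewer arrays or probe sets or a higher threshold make it plain.

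Without dim probe sets, the counts that moved by over 1.5 times were difference of dcl3-1 and rdr2-1 180. With a prior without trend, calls of these lists ended for the PPR list in rdr6-15 (median 0.056, adjusted p = 0.0567). With array weights, the counts that moved by over 1.5 times were hen1-1 6837, hyl1-2 3667, hst-15 7661, dcl2-1 1487, dcl3-1 3373, rdr1-1 4555, rdr2-1 3565, rdr6-15 3585, difference of the 2 dcl1-7 sets 2172, difference of hyl1-2 and hst-15 4157, difference of dcl1-7 first set and hen1-1 6898, difference of dcl3-1 and rdr2-1 2383, difference of the control sets of Col-0 10997, overlap of hyl1-2 and hst-15 2570, overlap of dcl1-7 and hyl1-2 1159 and overlap of dcl3-1 and rdr2-1 1408. With only the arrays of the control set, the counts that moved by over 1.5 times were hyl1-2 2803, hst-15 5499, difference of hyl1-2 and hst-15 2197, overlap of hyl1-2 and hst-15 2027, hen1-1 4804, difference of dcl1-7 first set and hen1-1 5664, dcl1-7 2598, difference of the 2 dcl1-7 sets 918, difference of the control sets of Ler 5806, overlap of dcl1-7 and hen1-1 694 and rdr1-1 115. With only the arrays of the control set, calls of these lists ended for the PPR list in rdr6-15 (median 0.056, adjusted p = 0.0748). With all arrays of the accession as controls, the counts that moved by over 1.5 times were dcl1-7 2875, dcl2-1 729, dcl3-1 1939, rdr2-1 727, rdr6-15 2081, overlap of dcl1-7 and hen1-1 1089 and overlap of dcl3-1 and rdr2-1 376. With all arrays of the accession as controls, calls of these lists ended for the miRNA target list in hyl1-2 (median 0.087, adjusted p = 0.0671). At a change of at least 2-fold, the counts that moved by over 1.5 times were dcl1-7 596, hen1-1 609, hyl1-2 136, hst-15 605, dcl2-1 63, dcl3-1 116, rdr1-1 27, rdr2-1 73, rdr6-15 242, difference of the 2 dcl1-7 sets 1061, difference of hyl1-2 and hst-15 215, difference of dcl1-7 first set and hen1-1 514, difference of dcl3-1 and rdr2-1 87, difference of the control sets of Ler 1483, difference of the control sets of Col-0 880, overlap of hyl1-2 and hst-15 98, overlap of dcl1-7 and hen1-1 248, overlap of dcl1-7 and hyl1-2 44 and overlap of dcl3-1 and rdr2-1 25. With an estimated correlation, calls of these lists ended for the miRNA target list in hyl1-2 (median 0.072, adjusted p = 0.0678), the miRNA target list in hst-15 (median 0.25, adjusted p = 0.0514), the PPR list in hyl1-2 (median 0.16, adjusted p = 0.132), the PPR list in rdr6-15 (median 0.056, adjusted p = 0.416), the difference of the list of PPR, hyl1-2 minus hst-15 (median 0.13, adjusted p = 0.283). With the first set alone, calls of these lists ended for the miRNA target list in dcl1-7 (median 0.32, adjusted p = 0.0546). Without Ler replicate 9 in any comparison, the counts that moved by over 1.5 times were hyl1-2 1283, dcl2-1 849, dcl3-1 2099, rdr1-1 675, rdr2-1 915, rdr6-15 854, difference of hyl1-2 and hst-15 1201, difference of dcl3-1 and rdr2-1 616, overlap of hyl1-2 and hst-15 910, overlap of dcl1-7 and hyl1-2 570 and overlap of dcl3-1 and rdr2-1 478. The values that turned were DFR in hen1-1 0.33, Hop3 in hyl1-2 0.33, AT5G49120 in dcl2-1 0.47, AT5G52390 in dcl3-1 0.14, AT5G48570 in rdr1-1 -0.17, CPUORF47 in rdr1-1 0.47, SPL in dcl1-7 0.062, heat-induced genes in hyl1-2 0.057, heat-induced genes in hst-15 0.065, heat-induced genes in dcl2-1 -0.089, heat-induced genes in dcl3-1 -0.13, cold and dehydration response in rdr1-1 0.058, heat-induced genes in rdr1-1 -0.12, pollen-expressed genes in rdr1-1 0.064, heat-induced genes in rdr2-1 -0.025, pollen-expressed genes in rdr2-1 0.031, chloroplast-encoded genes in rdr6-15 -0.0053. These were not called there and the cause was not tested.

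With each array of a comparison left out in turn, and no array outside it, the values ran over these ranges: hyl1-2 382 to 466, hst-15 1634 to 2298, miRNA target list in hyl1-2 0.0077 to 0.14, overlap of hyl1-2 and hst-15 264 to 444, overlap of dcl1-7 and hyl1-2 187 to 570, difference of the 2 dcl1-7 sets 1954 to 5062, list difference of miRNA target, dcl1-7 minus rdr6-15 0.11 to 0.26, dcl2-1 72 to 369, dcl3-1 193 to 694, rdr1-1 29 to 705, rdr2-1 181 to 358, overlap of dcl3-1 and rdr2-1 38 to 160, difference of dcl1-7 first set and hen1-1 1886 to 3126, difference of dcl3-1 and rdr2-1 141 to 568, difference of hyl1-2 and hst-15 330 to 937, list difference of PPR, hyl1-2 minus hst-15 0.067 to 0.17, rdr6-15 289 to 522, PPR list in rdr6-15 0.027 to 0.14. Of 50 called shifts of all lists, 29 kept their call without each array in turn. The list of trans-acting siRNA targets outside the PPR family had a named probe set for 0 of 11 genes, so its alternatives were not run, nor was the adding of an offset.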

Other observations

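The tests of joint normalization and of the Col-0 level of the rdr6-15 set, of drift of QQS between Col-0 sets and of QQS in dcl3-1 were chosen after their results were seen, as were all gene lists of this part, some of which hold genes named above, so that their direction is not independent evidence.

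Chloroplast-encoded genes rose in dcl1-7, with 35 of 69 called higher (median 0.57, camera adjusted p = 4.7e-11, and adjusted p = 0.421 with an estimated correlation), and in hen1-1, with 21 (median 0.51, camera adjusted p = 2.4e-11, and adjusted p = 0.421 with an estimated correlation). In the first-set Ler arrays, hen1-1 and the first dcl1-7 set, in this order, the mean signal of these genes was 6.99 ± 0.28, 7.56 ± 0.065 and 7.97 ± 0.08, the 3′ minus 5′ log2 signal of actin 1.62 ± 0.42, 1.45 ± 0.057 and 1.22 ± 0.10 and the log2 signal of 25S ribosomal RNA 5.81 ± 0.20, 6.01 ± 0.11 and 6.17 ± 0.032 (SD, n = 3 each). The 25S signal was not called in hen1-1 (0.20, adjusted p = 0.921) or in dcl1-7 over both sets (0.24, adjusted p = 0.736) by limma, and the actin signal was not tested. This list shifted down in dcl2-1 (median -0.27, adjusted p = 1.56e-08, and adjusted p = 0.521 with an estimated correlation, 2 of 69 called). The mean signal of these genes was 6.08 on dcl2-1 replicate 19, against 6.83 and 6.77 on the other dcl2-1 arrays, and without this array the list was at -0.16 (adjusted p = 0.0207). This array had the highest 3′ minus 5′ log2 signal of actin (2.23) and the lowest log2 signal of 25S ribosomal RNA (4.94) of all 44 arrays. The list shifted up in hyl1-2 (median 0.14, adjusted p = 0.0225, and adjusted p = 0.905 with an estimated correlation, limma called 0 of 69, with 3 higher and 0 lower at an unadjusted p under 0.05) and rdr6-15 (median 0.15, adjusted p = 0.049, and adjusted p = 0.905 with an estimated correlation, 1 of 69 called). On the 3 hyl1-2 arrays the 25S signal was 9.57, 9.20 and 9.85 and the mean signal of these genes 7.83, 7.32 and 7.96, in the same order, against 9.47 ± 0.12 and 7.55 ± 0.13 (SD, n = 3) in Col-0, and 25S was not called in hyl1-2 (0.073, adjusted p = 0.921). In rdr6-15 the 25S signal was called higher, at 7.89 ± 0.30 against 6.77 ± 0.19 in Col-0, while the mean signal of these genes was 7.14 ± 0.22 against 6.83 ± 0.073 (SD, n = 3 each). Genes of the cold and dehydration response fell in dcl1-7 (median -0.97, camera adjusted p = 0.00173, and adjusted p = 0.481 with an estimated correlation) and hen1-1 (median -1.15, camera adjusted p = 1.93e-06, and adjusted p = 0.203 with an estimated correlation), 5 and 6 of 9 called. In dcl1-7 the chloroplast-encoded list was not called in the second set alone (median 0.032, adjusted p = 0.481). In hen1-1 the chloroplast-encoded list was not called with all wild-type arrays of the accession as controls (median 0.017, adjusted p = 0.272). In dcl1-7 the cold and dehydration list was not called in the second set alone (median -0.13, adjusted p = 0.918). The call of the chloroplast-encoded list ended in hyl1-2 without Col-0 replicate 3 (median 0.075), without hyl1-2 replicate 30 (median 0.089) or without hyl1-2 replicate 32 (median 0.022), in rdr6-15 with the values as deposited (median 0.21), with array medians subtracted (median 0.23), with a prior without trend (median 0.15), with all wild-type arrays of the accession as controls (median -0.0053), without Col-0 replicate 39 (median 0.17), without Col-0 replicate 41 (median 0.17), without rdr6-15 replicate 43 (median 0.13) or without rdr6-15 replicate 44 (median 0.12). The cold and dehydration list also shifted down in rdr1-1 (median -0.43, adjusted p = 0.000802, and adjusted p = 0.421 with an estimated correlation, limma called 0 of 9, with 0 higher and 4 lower at an unadjusted p under 0.05). Its call ended in rdr1-1 with all wild-type arrays of the accession as controls (median 0.058) or without rdr1-1 replicate 35 (median -0.22). Of 14 SWEET sugar transporter genes 9 fell in dcl1-7 (median -0.85, camera adjusted p = 6.89e-07, and adjusted p = 0.192 with an estimated correlation), and of 15 pollen-expressed genes 11 (median -0.67, camera adjusted p = 1.58e-08, and adjusted p = 0.117 with an estimated correlation).

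The pollen-expressed list includes the mature pollen genes named above. It also shifted down in hen1-1 (median -0.48, adjusted p = 2.58e-06, and adjusted p = 0.203 with an estimated correlation, 8 of 15 called), hst-15 (median -0.63, adjusted p = 2.63e-07, and adjusted p = 0.189 with an estimated correlation, 9 of 15 called), hyl1-2 (median -0.19, adjusted p = 0.00107, and adjusted p = 0.421 with an estimated correlation, limma called 0 of 15, with 0 higher and 5 lower at an unadjusted p under 0.05), rdr1-1 (median -0.17, adjusted p = 0.0223, and adjusted p = 0.659 with an estimated correlation, limma called 0 of 15, with 0 higher and 2 lower at an unadjusted p under 0.05), rdr2-1 (median -0.28, adjusted p = 0.00335, and adjusted p = 0.506 with an estimated correlation, 1 of 15 called) and rdr6-15 (median -0.13, adjusted p = 0.0403, and adjusted p = 0.68 with an estimated correlation, limma called 0 of 15, with 0 higher and 3 lower at an unadjusted p under 0.05), and up in dcl3-1 (median 0.28, adjusted p = 0.00823, and adjusted p = 0.561 with an estimated correlation, 1 of 15 called). Its call ended in hyl1-2 without hyl1-2 replicate 31 (median -0.18), in rdr1-1 with only the arrays of the control set (median -0.17), with all wild-type arrays of the accession as controls (median 0.064), without Col-0 replicate 10 (median -0.12), without rdr1-1 replicate 34 (median -0.081) or without rdr1-1 replicate 35 (median -0.079), in rdr2-1 with all wild-type arrays of the accession as controls (median 0.031) or without rdr2-1 replicate 38 (median -0.13), in rdr6-15 with array weights (median -0.14), without Col-0 replicate 39 (median -0.096), without rdr6-15 replicate 42 (median -0.13), without rdr6-15 replicate 43 (median -0.12) or without rdr6-15 replicate 44 (median -0.11). The list of RALF-like peptide genes shifted down in dcl1-7 (median -0.18, adjusted p = 0.0365, and adjusted p = 0.349 with an estimated correlation, 2 of 10 called) and up in dcl3-1 (median 0.22, adjusted p = 0.0184, and adjusted p = 0.263 with an estimated correlation, limma called 0 of 10, with 3 higher and 0 lower at an unadjusted p under 0.05), and that of xyloglucan endotransglucosylase genes up in dcl3-1 (median 0.41, adjusted p = 0.00137, and adjusted p = 0.0552 with an estimated correlation, 3 of 9 called). The call of the RALF-like list ended in dcl1-7 with array weights (median -0.055), in the first set alone (median -0.10), in the second set alone (median -0.29), without Ler replicate 8 (median -0.20), without Ler replicate 9 (median -0.073) or without dcl1-7 replicate 17 (median -0.16), in dcl3-1 with all wild-type arrays of the accession as controls (median 0.30), without Col-0 replicate 11 (median 0.20) or without dcl3-1 replicate 21 (median 0.21). Without 1 array the median of the pollen-expressed list was -0.18 in rdr2-1 (Col-0 replicate 10) and -0.33 in rdr1-1 (rdr1-1 replicate 33), that of the chloroplast-encoded list 0.26 in hyl1-2 (hyl1-2 replicate 31) and 0.29 in rdr6-15 (rdr6-15 replicate 42), and that of the xyloglucan endotransglucosylase list 0.26 in dcl3-1 (Col-0 replicate 11).

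Heat-induced genes fell in hyl1-2 (median -0.38, camera adjusted p = 3.06e-07, and adjusted p = 0.00409 with an estimated correlation), 4 of 8, and in hst-15 (median -0.43, camera adjusted p = 4.7e-05, and adjusted p = 0.0209 with an estimated correlation), 5. The list shifted up in dcl2-1 (median 0.12, adjusted p = 0.00142, and adjusted p = 0.0736 with an estimated correlation, 3 of 8 called), dcl3-1 (median 0.11, adjusted p = 0.0338, and adjusted p = 0.259 with an estimated correlation, 2 of 8 called), rdr1-1 (median 0.19, adjusted p = 0.0153, and adjusted p = 0.199 with an estimated correlation, 1 of 8 called) and rdr2-1 (median 0.25, adjusted p = 0.000539, and adjusted p = 0.0552 with an estimated correlation, 2 of 8 called). These calls ended in dcl2-1 with all wild-type arrays of the accession as controls (median -0.089), in dcl3-1 with array weights (median 0.091), with all wild-type arrays of the accession as controls (median -0.13), without Col-0 replicate 11 (median 0.085) or without dcl3-1 replicate 21 (median 0.079), in rdr1-1 with array weights (median 0.15), with all wild-type arrays of the accession as controls (median -0.12), without Col-0 replicate 11 (median 0.13) or without rdr1-1 replicate 33 (median 0.15), in rdr2-1 with all wild-type arrays of the accession as controls (median -0.025). With all wild-type arrays of the accession as controls the falls turned too, to 0.057 in hyl1-2 and 0.065 in hst-15, and were not called. Both falls were against one set of Col-0 arrays and all these rises against another. A difference in level between these Col-0 sets thus cannot be told from effects of the mutants. Of 989 annotated pseudogenes 11 were called higher and 1 lower in rdr2-1, and 77 higher and 24 lower in dcl1-7. The list was not called in either (camera adjusted p = 0.858 and 0.269), and of all 22746 probe sets 262 were called higher and 196 lower in rdr2-1, and 3044 and 2809 in dcl1-7. Among the 100 measured genes nearest each mutated gene in TAIR10.1, the share called was not called different from elsewhere by 2-sided Fisher's exact tests, with the smallest p in dcl3-1 (p = 0.0552, adjusted p = 0.497).

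A list of early elicitor and wound genes, drawn up from genes seen in these data, shifted down in rdr6-15 (median -1.05, adjusted p = 8.18e-24, and adjusted p = 0.00409 with an estimated correlation, 9 of 11 called) and up in dcl1-7 (median 0.73, adjusted p = 4.7e-05, and adjusted p = 0.355 with an estimated correlation, 7 of 11 called) and hst-15 (median 0.76, adjusted p = 2.02e-07, and adjusted p = 0.203 with an estimated correlation, 8 of 11 called). Its call ended in dcl1-7 in the first set alone (median 0.20). Its median in hst-15 was 1.29 without hst-15 replicate 27. Of the 233 probe sets at least 2-fold lower in rdr6-15, 124 were called higher and 7 lower in hst-15, and 121 higher and 10 lower in dcl1-7.

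In rdr6-15 233 probe sets were at least 2-fold lower. A separate normalization of this set by the authors, inferred from its deposited medians and not given in the sources used here, stays open. The values as deposited, with 246 such probe sets, would carry it. Joint normalization, after which 230 of these 246 stayed at least 2-fold lower, moved the contrast by a median of only 0.018, against a median SE of 0.12. A candidate explanation is high levels in the Col-0 arrays of this set, whose excess over the other Col-0 sets made up 0.830 of the median fall, a level set across sets whose deposited medians stood apart. The 233 probe sets were chosen by their fall below these same Col-0 arrays, which favours such an excess in advance, so the share cannot decide. In rdr6-15 these probe sets lay at a median of -0.39 against the other Col-0 sets. Another candidate explanation is transcripts that vary from array to array: the median residual SD outside the set was 0.385, against a median of 0.162 over 10000 random lists of like mean signal, 100% of which lay lower. The random lists were not matched on size of change. Choosing probe sets by a fall of at least 2-fold may favour variable transcripts in advance, so this comparison cannot decide either. An effect of rdr6-15 itself stays open.

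QQS was higher in rdr2-1 and dcl2-1. Against a change of the chromosome segment, 0 of the 8 nearest measured genes were called by limma in rdr2-1, 0 of them at an unadjusted p under 0.05. Against loss of siRNAs that need both RDR2 and DCL3, the log2 fold change in dcl3-1 was -0.85 and not called. This value does not speak to siRNAs that need RDR2 but not DCL3, and the nearest genes do not speak to a change confined to QQS. Drift between plant lines may contribute, since the range of the Col-0 set means was 0.594 of the rdr2-1 change, but that range rests on the Col-0 arrays of the rdr6-15 set (9.81, against 7.65 and 7.84), whose deposited medians stood apart.

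Other splits of the same arrays were counted for each comparison. For dcl1-7, 2 of 100 splits drawn within its sets, the real one included, gave as many calls as its 5853, a share under 0.05. The other, with 6767, set the first-set Ler arrays and Ler replicates 8 and 9 in place of dcl1-7. Since replicate arrays may be technical, this share holds for these arrays only and does not exclude chance between plants. For comparisons of 3 arrays with 3, the 10 splits are too few for a share under 0.05, and 1 split gave as many calls in each. The real values and the highest of the other splits were 3107 and 1 for hen1-1, 710 and 0 for hyl1-2, 2554 and 172 for hst-15, 363 and 2 for dcl2-1, 965 and 1 for dcl3-1, 182 and 14 for rdr1-1, 458 and 16 for rdr2-1, 548 and 0 for rdr6-15, 750 and 115 for difference of hyl1-2 and hst-15, 3451 and 0 for difference of dcl1-7 first set and hen1-1, 390 and 4 for difference of dcl3-1 and rdr2-1, 9397 and 3616 for difference of the control sets of Ler, 6369 and 0 for difference of the control sets of Col-0.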
